A study of Escherichia coli with 12 samples.

How the data were processed

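Total RNA of Escherichia coli DH1 grown in M9 MOPS medium was compared between cells given 0.8% n-butanol and unstressed cells at 0, 30, 80 and 195 min after the addition, per the labels. There were 12 two-colour arrays, 3 biological replicates at each of 4 times, and each array held the treated and the unstressed RNA of 1 time. Per the labels, the treated RNA carried Alexa555, read at 532 nm, and the unstressed RNA carried Alexa647, read at 635 nm, on every array. No dye swap was made, so a gene-specific dye effect stays in a ratio at 1 time and cancels in a change of the ratio from 0 min.

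The intensity values were pixel medians that the authors read with a GenePix 4200A scanner and GenePix Pro 6.1.0.2, per the file headers. The same headers record 1 normalization factor per channel and array, already applied to these intensities. They were not background subtracted. The deposited score column holds a flag for each spot, with -100 for a bad spot and -50 for a spot not found. The deposited percent columns give the share of saturated pixels of each spot. The authors' deposited value table holds log2 ratios in the direction of butanol over unstressed. That scale and direction were found by setting each column against the scanner values of its array: r across genes was 0.938 to 0.992, the slopes were 1.03 to 1.39 and the column medians were -0.0292 to 0.0226. How that table was normalized, and how its spots were combined, is not given in the sources used here, so it served only as an alternative.

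Each array had 13872 spots in 48 blocks, of which 12867 belonged to 4289 genes, with 1 probe per gene printed 3 times, and 1005 were controls. Background was corrected with normexp (offset 50), and the log2 ratios were normalized within each array by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Controls and spots with a flag below 0 had weight 0 in the loess and were then left out, and the remaining spots of a gene were averaged. Genes measured on at least 2 arrays at every time were tested, which left 4260 genes and removed 29. The use of pixel medians, the rule on flags and the limit for a signal above background (local background plus 2 SD) were set after the columns of the files had been seen. Array IDs were named through the reference table of assembly ASM584v2, which is the K-12 strain MG1655 and not DH1: 4120 IDs matched a current locus tag, 7 matched a synonym, and 162 kept the array's own name. No gene named in the text was below background or saturated on every array of a time.

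A single limma model with 1 mean per time was fitted to all 12 arrays, so that the times shared 1 estimate of the spread. It gave the ratio against 0 at each time, the change of the ratio from 0 min to each later time, the change from 30 to 195 min, and an F test of equal ratios at 30, 80 and 195 min. P-values were adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. All tests were two-sided. Values are given as the mean log2 ratio ± SD over arrays. The number of arrays limits the precision.

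The comparisons, the alternatives, 34 gene lists and the rule for naming genes were fixed before the data were examined. At 30, 80 and 195 min, the rule named the 10 highest and the 10 lowest mean ratios among genes past the ratio test, with the same direction on all 3 arrays and a change from 0 min of the same sign past its own test. It passed 213 genes higher and 193 lower at 30 min, 137 and 186 at 80 min, and 129 and 106 at 195 min. For the change from 30 to 195 min it named the 5 highest and the 5 lowest changes past that test. From each list it allowed up to 4 members per time that passed the ratio test, and all members of lists with at most 6.

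The lists covered respiration and ATP synthesis, stress responses, the envelope, transport, the synthesis of amino acids, nucleotides and lipids, motility, ribosomes, fermentation, alcohol and aldehyde enzymes, and central carbon use. Of their members, oxyS, ecnB and araH were not measured. Each list was tested with camera in limma on the moderated statistics, with a preset correlation of 0.01 between genes, adjusted over 136 tests of lists and times. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run on the 3644 genes measured on every array. Counts of list members are given over all genes and adjusted over the list alone. A list's median, mean and test can differ in sign, which is said for the ratio at each time and for the change from 30 to 195 min.

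The steps were tested on simulated data for the comparison at 30 min over 4260 genes. At a simulated fold of 1.41, 6 of 67 changed genes were recovered (8.96%), at a fold of 2, 47 of 67 (70.1%), and at a fold of 4, 63 of 66 (95.5%). There were 4 false calls among 120, and 0 calls at the other 3 times, where limma was given no change. A shifted list was called by camera with an adjusted p of 4.08e-20, and 0 of 33 random lists were called. Noise was simulated independently for each gene and with the same spread on every array. The simulation therefore could not show false calls of lists whose genes are correlated, and the estimated correlation of ribosomal proteins at 0 min was 0.914. Nor could it show false or missed calls of genes where the spread differs between arrays. For the median gene, the SD among the 3 real arrays of a time was 0.144 at 30 min and 0.357 at 195 min.

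The alternatives planned in advance were no background correction, plain subtraction, median centring, print-tip loess, scaling between arrays, the deposited value table, a filter on dim spots, array weights, fits of only the times compared, the replicate number or the scan day as a block, a threshold of at least 1 on the log2 scale, other list tests, and leaving out each array in turn. Scans fell on 3 days. Day 1 held replicate 1 of every time, day 2 held replicate 2 of every time with replicate 3 of 0 and 30 min, and day 3 held replicate 3 of 80 and 195 min. Alternatives chosen after seeing the data were spots not found kept, pixel means, both arrays that stood apart left out, and the replicate block together with both left out. Using the brightest probe of each gene could not be run, because each gene has 1 probe.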

Results

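The transcripts of 4289 genes were measured in Escherichia coli DH1, a K-12 laboratory strain, with and without 0.8% n-butanol, a 4-carbon alcohol that cells can be engineered to make as a fuel. Cells with and without butanol were compared at 4 times, 0, 30, 80 and 195 min, with 3 biological replicates at each. Each value is the log2 ratio of butanol over unstressed cells on 1 array, so a positive value means more transcript in butanol. For a ratio at 1 time, rose and fell mean above and below 0, not a change with time in butanol-treated cells. The median spot intensity of an array was 279 to 1045 in the butanol channel and 306 to 1022 in the unstressed channel, over local backgrounds of 20 to 90 and 53 to 136. Replicate 2 at 195 min gave values for 3659 genes, after 1982 of its spots had been marked bad in the file. The other arrays gave values for 4241 to 4286 genes.

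The arrays labelled 0 min replicate 1 and 195 min replicate 1 stood apart from the rest. The SD of the ratios over genes was 0.991 on 0 min replicate 1, against 0.203 and 0.2 on the other arrays of that time. Across genes, which are not independent replicates, 195 min replicate 1 had r = 0.0466 with the mean of the other arrays of its time, and those had r = 0.923 with each other. The r between both arrays that stood apart was -0.668, and the direction of each was kept because the labels state the dyes. At 30 min r between arrays was 0.872 to 0.940, and at 80 min it was 0.776 to 0.843.

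**Figure D1:**
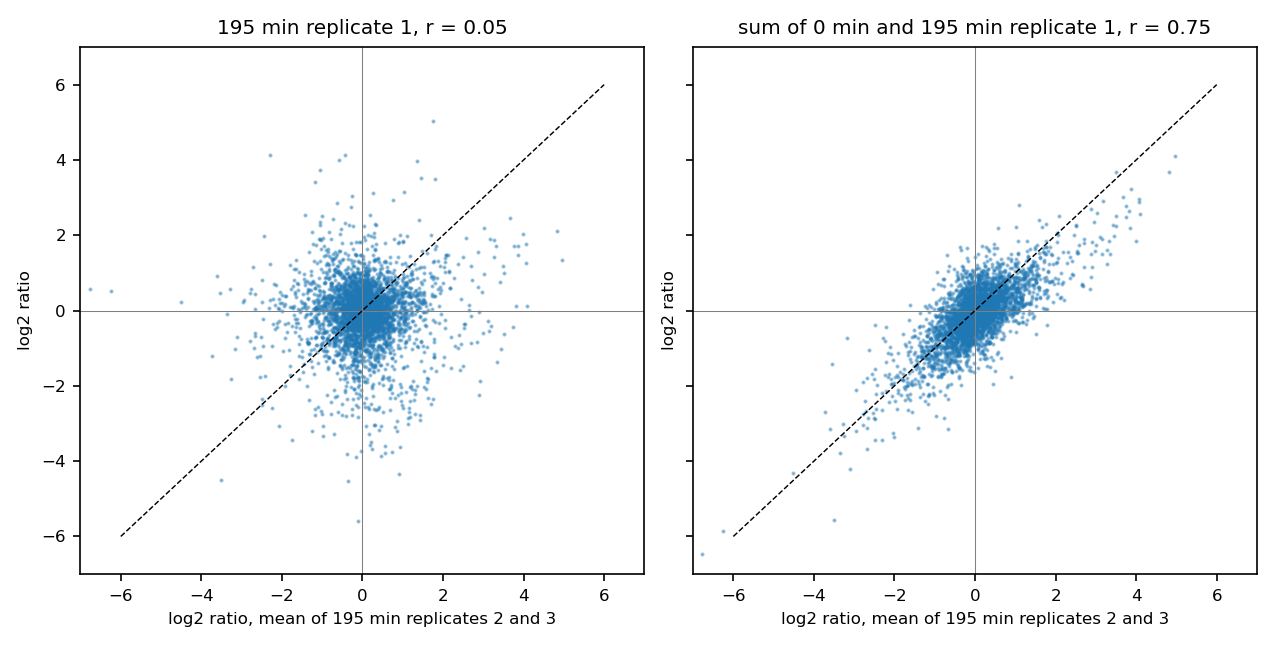
Each point is 1 gene, with the mean log2 ratio of 195 min replicates 2 and 3 on the horizontal axis and, on the vertical axis, the ratio of 195 min replicate 1 (left) or its sum with that of 0 min replicate 1 (right), and the dashed line marks equality. Pearson r across 3650 genes was 0.0466 for replicate 1 alone and 0.747 for the sum.

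**Figure D2:**
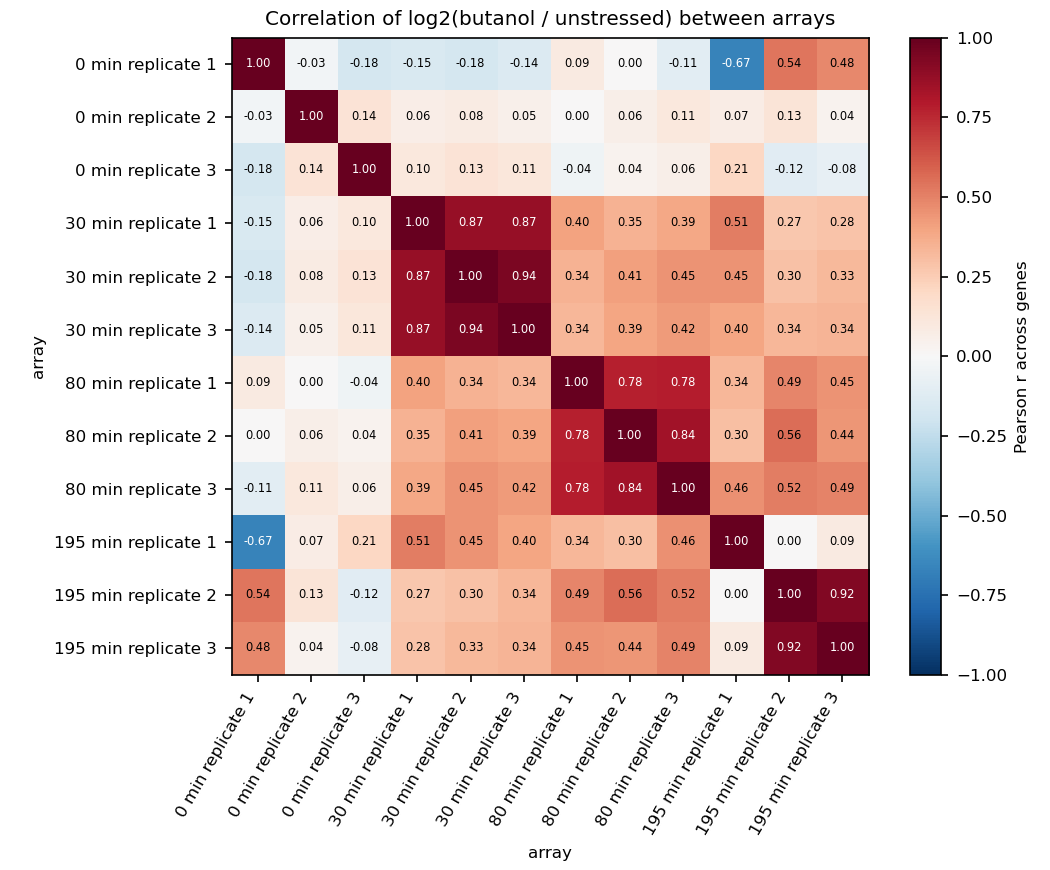
Pearson r across genes between the log2 ratios of all 12 arrays, with arrays on both axes in order of time and replicate. Arrays of 30 and 80 min form blocks of high r, and replicate 1 of 0 and 195 min has r = -0.668 with each other.

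At 0 min, the comparison asks whether treated and unstressed cultures differed before butanol had acted. Ribosomal protein genes had a median ratio of 2.23 on replicate 1 and of 0.02 and -0.04 on the others, and general stress genes controlled by sigma S had medians of -2.13, 0.06 and 0.28. Camera set 9 of the 34 lists apart. The lists of ribosomal proteins, ATP synthase, the TCA cycle, branched-chain amino acid synthesis and other sugar uptake were higher. Those of heat shock, sigma S, histidine synthesis and methionine synthesis were lower. The lowest of the 34 adjusted p-values was 0.688 with an estimated correlation. Of 4260 genes, 0 passed limma's test, and 132 had an unadjusted p under 0.05. With both arrays that stood apart left out, limma again called 0 genes and 112 had an unadjusted p under 0.05. Camera then set 14 lists apart, and 0 with an estimated correlation (lowest adjusted p = 0.305). The lowest camera adjusted p-values were those of arginine synthesis (median -0.38, 2.33e-09), anaerobic respiration and fermentation (0.16, 4.08e-09), purine synthesis (-0.24, 4.76e-09), pyrimidine synthesis (-0.16, 1.46e-06) and acid resistance (0.25, 4.35e-06), and methionine synthesis stayed lower (-0.13, 0.005). Arginine genes thus had medians of -0.39 and -0.27 on 0 min replicates 2 and 3. Of the lists set apart with all arrays, the medians in that fit were -0.01 for ribosomal proteins, 0.11 for ATP synthase, -0.05 for the TCA cycle, 0.09 for heat shock, 0.10 for sigma S and 0.05 for histidine synthesis. Among them camera called sigma S higher (adjusted p = 0.00343) and the TCA cycle lower (0.0116), both opposite to the call with all arrays. Other sugar uptake (0.0337) and branched-chain synthesis (0.0474) stayed higher. With all arrays the signs of the median and of the mean or the test differed at 0 min for sigma E, multidrug efflux, osmotic stress, iron uptake and the anaerobic list, and camera called none of these.

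At 30 min, the comparison asks how cells had responded shortly after the addition. The transcript of asr (b1597), an acid shock protein, was 32.1-fold higher in butanol (SD 0.46 on the log2 scale, n = 3), and that of the outer membrane porin ompF (b0929) was 33.3-fold lower (-5.06 ± 0.12, n = 3). Also higher were the pyruvate transporter btsT (b4354) at 3.89 ± 1.64, the sorbitol uptake and use genes srlA, srlD and srlB at 3.17, 2.92 and 2.91, the ribosome modulation factor rmf (b0953) at 3.15 ± 0.23, the pyruvate dehydrogenase subunit aceE (b0114) at 3.04 ± 0.23, ydcH at 2.93, and marA (b1531), a regulator of multidrug resistance, at 2.70 ± 0.49. Among genes that met the naming rule, the lowest after ompF were the methionine synthase metE (b3829) at -3.84 ± 0.34, yagU at -3.51, ilvG, leuA and ilvC of branched-chain amino acid synthesis at -2.65, -2.56 and -2.55, the sulfate-binding protein sbp at -2.56, hcp at -2.44, elfD at -2.42 and metF at -2.41. Their adjusted p-values were 6.67e-06 to 0.0101.

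Some genes of peptide, maltose and other sugar uptake rose at 30 min. In the oligopeptide and dipeptide list 5 of 12 rose, with 5 adjusted over the list alone, among them oppB (2.41 ± 0.05), oppA (2.40 ± 0.39) and oppD (2.32 ± 0.16) of the oligopeptide transporter. The list had a camera adjusted p of 1.52e-08, and adjusted p = 0.65 with an estimated correlation. In the maltose list 5 of 14 rose, and 7 adjusted over the list alone, with malE at 3.92 ± 0.05, malF at 3.32 ± 0.27 and the porin lamB at 2.54 ± 0.14 (camera adjusted p = 0.000286, adjusted p = 0.66 with an estimated correlation). Among other sugar uptake genes 10 of 32 rose and 1 fell, with 16 and 1 adjusted over the list alone, led by manY, manZ and manX of the mannose transporter at 2.68, 2.63 and 2.60 (camera adjusted p = 0.000307, adjusted p = 0.709 with an estimated correlation).

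Some members of the Cpx, oxidative stress and heat shock lists rose at 30 min, while camera did not set apart the sigma S list (adjusted p = 0.716) or the acid resistance list (adjusted p = 0.31). In the Cpx envelope stress list 6 of 14 rose and 1 fell, with 6 and 2 adjusted over the list alone. Its leading members were the periplasmic proteins cpxP (b3913, 2.54 ± 0.46) and spy (b1743, 2.29 ± 0.37), and its camera adjusted p was 0.00403, with adjusted p = 0.691 with an estimated correlation. In the oxidative stress list 9 of 30 rose and 1 fell, with the same counts adjusted over the list alone, and the largest ratios were those of the regulators marA and soxS (1.56 ± 0.32) and of marB (1.63 ± 0.73). Of 21 heat shock genes 6 rose, with 6 adjusted over the list alone, among them the chaperonin groL (1.04 ± 0.20) and rpoH (0.93 ± 0.02), which encodes sigma 32. Of 20 alcohol and aldehyde enzymes 6 rose, with 6 adjusted over the list alone, led by the reductase yqhD (2.51 ± 0.16) and the dehydrogenase aldB (2.23 ± 0.63). In the anaerobic respiration and fermentation list 9 of 34 rose, with 9 adjusted over the list alone, and the highest was ndh (1.77 ± 0.05), an NADH dehydrogenase of aerobic respiration. The camera adjusted p-values of these 4 lists were 0.00563, 0.035, 0.0316 and 0.0349, and each list's call was lost with an estimated correlation (adjusted p = 0.688, 0.798, 0.688 and 0.727).

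Genes of arginine, branched-chain amino acid, cysteine, methionine and purine synthesis were among those that fell at 30 min, while camera did not set apart the histidine list (adjusted p = 0.835) or the tryptophan and aromatic list (adjusted p = 0.267), where 5 of 19 fell and 3 rose. Of 12 arginine genes 8 fell, with 8 adjusted over the list alone, among them argG (-2.35 ± 0.29) and argD (b3359, -2.31 ± 0.27), and the camera adjusted p was 9.5e-08, with adjusted p = 0.688 with an estimated correlation. The median ratio of the arginine list was -1.25 at 30 min, and its median change from 0 min was -1.06, or -0.67 without both arrays that stood apart. Of 14 branched-chain genes 9 fell, with 9 adjusted over the list alone (camera adjusted p = 1.04e-05, adjusted p = 0.688 with an estimated correlation). Of 22 genes of cysteine synthesis and sulfate uptake 10 fell, with 10 adjusted over the list alone, including cysD (-2.04 ± 0.19). That list had a camera adjusted p of 3.64e-05, and adjusted p = 0.65 with an estimated correlation. Of 13 methionine genes 4 fell, and 5 adjusted over the list alone, with metE and metF lowest (camera adjusted p = 0.00228, adjusted p = 0.688 with an estimated correlation). Of 14 purine genes 6 fell, and 10 adjusted over the list alone, led by guaB (-1.71 ± 0.89) and guaA (-1.32 ± 0.11), with a camera adjusted p of 0.00167 and adjusted p = 0.688 with an estimated correlation.

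Ribosomal protein genes had a median ratio of -1.34 at 30 min. Of 54 members 7 fell, and 26 adjusted over the list alone, with rpmC (-2.03 ± 0.40) and rplS (-1.90 ± 0.32) lowest. In the fit without both arrays that stood apart 50 of the 54 fell. The list's camera adjusted p was 1.08e-06, and adjusted p = 0.709 with an estimated correlation. Of 50 flagella and chemotaxis genes 11 fell, including flgB (-2.18 ± 0.71) and the flagellin gene fliC (-1.31 ± 0.46), and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00133, adjusted p = 0.688 with an estimated correlation). Of 37 iron uptake genes 8 fell, with 8 adjusted over the list alone, led by feoA (b3408, -1.78 ± 0.42) of ferrous iron uptake and exbD (-1.75 ± 0.51). The camera adjusted p of the iron list was 0.0364, and adjusted p = 0.755 with an estimated correlation.

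The TCA cycle list had a median of -0.67 at 30 min, below 0 on each of the 3 arrays, and was not called (camera adjusted p = 0.168). Its change from 0 min was called (median -1.48, camera adjusted p = 0.0199), but with an estimated correlation no list's change was (lowest adjusted p = 0.639). The TCA median at 0 min was 2.415 on replicate 1 and -0.06 and -0.09 on the others, which enlarged that change. The ratio at 30 min was called without both arrays that stood apart, where 13 of 15 genes fell and 1 rose (camera adjusted p = 1.69e-05, adjusted p = 0.473 with an estimated correlation).

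In all, limma called 894 of 4260 genes at 30 min, 483 higher and 411 lower, and 412 changed from 0 min, 216 upward and 196 downward. Leaving out both arrays that stood apart gave 1830 genes, which held all 894 in the same direction, and 968 changes. The camera calls of the oxidative stress, alcohol and aldehyde, and iron lists were lost in that fit (adjusted p = 0.193, 0.108 and 0.171). In the change from 0 min the calls of the methionine, iron and anaerobic lists were lost (adjusted p = 0.0703, 0.0555 and 0.0578), and the median of the methionine list, lower at 0 min already, was -0.12 against -0.36 for the ratio. With scan day as a block 595 genes passed.

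At 80 min, the comparison asks which of these differences were present later. Among genes that met the naming rule, with a change from 0 min past its own test, the highest ratios were those of cpxP (15.5-fold, 3.96 ± 0.21, SD, n = 3) and of b3914 (3.66 ± 0.09, n = 3), which the reference table does not name. They were followed by asr (2.98 ± 0.61), rmf (2.80 ± 0.13), aldB (2.75 ± 0.98), the formate channel focA (2.19 ± 0.21), spy (2.17 ± 0.65), the sensor kinase evgS (2.17 ± 0.93), the nitrate reductase subunit narZ (2.16 ± 0.43) and ybgS (2.15 ± 0.23). The lowest among genes that met the same rule were metE (16.9-fold lower, -4.08 ± 0.89), the outer membrane protease ompT (-3.77 ± 0.31), envY (-3.26 ± 0.38), hisG of histidine synthesis (-3.17 ± 0.27), leuD (-3.04 ± 0.17), yagU (-2.95 ± 1.68), metF (-2.73 ± 0.07), hcp (-2.57 ± 0.40), the alanine exporter alaE (-2.53 ± 0.89) and argD (-2.35 ± 0.29). Their adjusted p-values were 3.72e-05 to 0.0149.

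Members of the NADH dehydrogenase I, TCA cycle, Cpx, efflux, osmotic stress and oligopeptide lists had higher ratios of butanol over unstressed at 80 min. Of 13 genes of NADH dehydrogenase I 6 rose, and 9 adjusted over the list alone, with nuoI (1.94 ± 0.33) and nuoH (1.75 ± 0.57) highest and a list median of 1.56 (camera adjusted p = 0.000349, adjusted p = 0.709 with an estimated correlation). Of 15 TCA cycle genes 2 rose, acnA (1.91 ± 0.28) and fumC (0.90 ± 0.39), with 2 adjusted over the list alone. In the Cpx list 9 of 14 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000122, adjusted p = 0.688 with an estimated correlation). Of 22 multidrug efflux genes 9 rose, and 10 adjusted over the list alone, led by acrB (2.18 ± 0.78) and acrA (1.29 ± 0.56) of the main efflux pump. Of 15 osmotic stress genes 3 rose and 1 fell, with 4 and 1 adjusted over the list alone, and betI (1.15 ± 0.38) and betB (1.13 ± 0.68) of betaine synthesis were highest. In the oligopeptide and dipeptide list 5 rose and 1 fell, with 6 and 2 adjusted over the list alone, led by oppD (1.93 ± 0.46). The camera adjusted p-values of the TCA, efflux, osmotic and oligopeptide lists were 0.0163, 0.00247, 0.0328 and 0.00218. Each of those calls was lost with an estimated correlation (adjusted p = 0.755, 0.66, 0.688 and 0.688).

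Amino acid synthesis was lower at 80 min in 5 lists. Of 13 methionine genes 11 fell, and 12 adjusted over the list alone, with metA (-2.31 ± 0.32) and metI (-1.29 ± 0.22) next to metE and metF (camera adjusted p = 5.33e-16, adjusted p = 0.416 with an estimated correlation). Of 12 arginine genes 9 fell, and 10 adjusted over the list alone, with argC at -2.43 ± 0.95 (camera adjusted p = 7.83e-09, adjusted p = 0.688 with an estimated correlation). Of 8 histidine genes 5 fell, and 6 adjusted over the list alone, with hisD (-2.69 ± 0.18) next to hisG. Of 19 tryptophan and aromatic genes 9 fell, and 12 adjusted over the list alone, led by trpE (b1264, -3.26 ± 0.49). Of 14 branched-chain genes 5 fell, and 6 adjusted over the list alone, with leuC at -1.69 ± 0.06. The camera adjusted p-values of the histidine, aromatic and branched-chain lists were 9.09e-05, 5.27e-05 and 0.0183, and these calls were lost with an estimated correlation (adjusted p = 0.688, 0.688 and 0.755).

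Of 34 anaerobic respiration and fermentation genes 9 fell at 80 min, among them dmsA (-1.77 ± 0.37) and hybO (-1.36 ± 0.37), and 2 rose, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.709 with an estimated correlation). Of 22 genes of glycolysis and acetate use 6 fell, including gapA (-1.03 ± 0.16), and 2 rose, aceE (1.69 ± 0.50) and aceF (1.21 ± 0.59), with 8 and 2 adjusted over the list alone (camera adjusted p = 0.0429, adjusted p = 0.709 with an estimated correlation). Of 54 ribosomal protein genes 2 fell, rplS (-1.98 ± 0.61) and rpmE (-1.15 ± 0.19), and 0 adjusted over the list alone in limma's test. When both arrays that stood apart were left out, 38 fell and 1 rose. The ribosomal list had a median of -0.74 and a camera adjusted p of 0.00676, with adjusted p = 0.89 with an estimated correlation.

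In all, limma called 828 genes at 80 min, 402 higher and 426 lower, and 337 changed from 0 min, 148 upward and 189 downward. Leaving out both arrays that stood apart gave 2032, which held all 828 in the same direction, and 1023 changes. The call of the glycolysis and acetate list was lost in that fit (adjusted p = 0.0859). In the change from 0 min its call and those of the TCA cycle and osmotic stress were lost (adjusted p = 0.0551, 0.271 and 0.0502), and the TCA median was 0.20 against 0.90 for the ratio. The TCA median at 0 min was 2.415 on replicate 1, which stood apart, and -0.06 and -0.09 on the others, so that array lowered the change. With only median centring 30.5% of the changes from 0 min were upward, against 43.9% here, and with scan day as a block 809 genes passed at 80 min.

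At 195 min, the comparison asks about the latest time measured. Among genes that met the naming rule, with a change from 0 min past its own test, the highest ratios were those of dhaK (b1200, 15.1-fold, 3.92 ± 1.58, SD, n = 3), dhaL (3.30 ± 1.33) and dhaM (3.27 ± 0.71) of dihydroxyacetone kinase, btsT (3.34 ± 1.21) and yjiX (2.78 ± 0.94), gatZ (3.16 ± 1.28) and gatA (3.07 ± 1.18) of galactitol use, the ketodeoxygluconate transporter kdgT (3.06 ± 1.39), aldB (2.81 ± 0.82) and the copper sensor cusS (2.75 ± 0.56). The lowest among genes that met the same rule were metE (14.3-fold lower, -3.84 ± 0.86), argD (-2.51 ± 0.26), hcp (-2.45 ± 0.28), sbp (-2.40 ± 0.57), the glutamate dehydrogenase gdhA (-2.36 ± 0.50), the DNA-binding protein hupA (-2.31 ± 0.98), exoD (-2.19 ± 0.54), argH (-2.16 ± 0.85), argG (-1.95 ± 0.32) and the hydrogenase subunit hycE (-1.81 ± 1.10). Their adjusted p-values were 2.31e-05 to 0.00305. The rule that named these genes required the same direction on replicate 1, which stood apart, and its ratio was 2.12 for dhaK and -4.50 for metE. It thus passed over genes whose ratio on replicate 1 went against that on the other arrays, however large. The median of the cytochrome bo oxidase list was -1.571 on replicate 1 and 3.129 and 2.255 on the others. That of ATP synthase was -1.845, against 1.757 and 1.411.

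Of 13 genes of NADH dehydrogenase I 5 rose at 195 min, and 12 adjusted over the list alone, with nuoI at 1.91 ± 1.71 (camera adjusted p = 0.000307, adjusted p = 0.709 with an estimated correlation). The median of that list was -0.29 on replicate 1 and 2.91 and 2.23 on the others. In the oligopeptide and dipeptide list 5 of 12 rose, with 5 adjusted over the list alone, led by oppB (1.62 ± 0.32) and oppA (1.41 ± 0.26), and its camera adjusted p was 0.00012, with adjusted p = 0.65 with an estimated correlation. Among other sugar uptake genes 10 of 32 rose and 1 fell, with 13 and 2 adjusted over the list alone, led by the ribose transporter gene rbsA (3.75 ± 2.11). In the Cpx list 5 rose and 2 fell, with 8 and 2 adjusted over the list alone, including cpxP (2.53 ± 1.54) and spy (1.52 ± 0.06). Of 6 phage shock genes 3 rose, pspE (1.10 ± 0.78), pspC (0.71 ± 0.35) and pspB (0.70 ± 0.37), and 4 adjusted over the list alone. The camera adjusted p-values of the sugar, Cpx and phage shock lists were 0.00232, 0.0455 and 0.0332, and these calls were lost with an estimated correlation (adjusted p = 0.709, 0.709 and 0.688).

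Of 12 arginine genes 10 fell at 195 min, and 11 adjusted over the list alone, with a list median of -1.50 (camera adjusted p = 5.99e-13, adjusted p = 0.66 with an estimated correlation). Of 8 histidine genes 7 fell, and 8 adjusted over the list alone, with hisG and hisD both at -2.13 (camera adjusted p = 0.000114, adjusted p = 0.688 with an estimated correlation). Of 13 methionine genes 6 fell, with 6 adjusted over the list alone, including metQ (-1.59 ± 0.37) of methionine uptake (camera adjusted p = 7.83e-09, adjusted p = 0.65 with an estimated correlation). Of 22 glycolysis and acetate genes 10 fell, including pfkB (-1.20 ± 0.33) and ppc (-1.09 ± 0.45), and adjusted over the list alone 12 fell and 4 rose. Of 19 tryptophan and aromatic genes 6 fell, and 7 adjusted over the list alone, with trpE at -2.31 ± 1.44. Of 22 cysteine and sulfate genes 6 fell, with 6 adjusted over the list alone, and of 14 purine genes 2 fell, purC (-0.77 ± 0.73) and purA (-0.40 ± 0.28), and 3 adjusted over the list alone. The camera adjusted p-values of these last 4 lists were 0.00192, 0.00126, 0.035 and 0.0203, and their calls were lost with an estimated correlation (adjusted p = 0.688, 0.688, 0.688 and 0.709).

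Ribosomal protein genes had a median ratio of -2.48 on 195 min replicate 1 and of 0.48 and 0.31 on the other arrays of that time. With all 3 arrays the median was -0.58, 3 of 54 fell, and 0 adjusted over the list alone in limma's test (camera adjusted p = 0.035, adjusted p = 0.904 with an estimated correlation). Without both arrays that stood apart the median was 0.41, with a higher ratio for 23 genes and a lower ratio for 6. The median change from 0 min on replicates 2 and 3 was -2.24 and -2.11 in unstressed cells and -1.59 and -1.75 in butanol, so neither channel rose. Other list medians moved with 195 min replicate 1 as well. From all arrays to the fit without both, the median went from 1.58 to 2.55 for NADH dehydrogenase I, from 1.18 to 2.69 for cytochrome bo oxidase, from 0.31 to 1.62 for ATP synthase, from 0.13 to 1.16 for the TCA cycle and from -0.33 to -0.88 for sigma S.

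In all, limma called 700 genes at 195 min, 375 higher and 325 lower, and 241 changed from 0 min, 134 upward and 107 downward. Leaving out both arrays that stood apart gave 1769, which held 676 of the 700 in the same direction, and 1277 changes. The calls of the phage shock, aromatic, cysteine, purine and glycolysis lists were lost in that fit (adjusted p = 0.108, 0.108, 0.139, 0.212 and 0.148). Ribosomal proteins, called lower with all arrays, had a median above 0 there. In the change from 0 min the calls of the other sugar, Cpx, phage shock and cysteine lists were lost (adjusted p = 0.104, 0.104, 0.0502 and 0.132). A fit of the 195 min arrays alone called 0 genes in limma, against 700, with 668 at an unadjusted p under 0.05, against 1260, and with scan day as a block 656 passed.

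**Figure D3:**
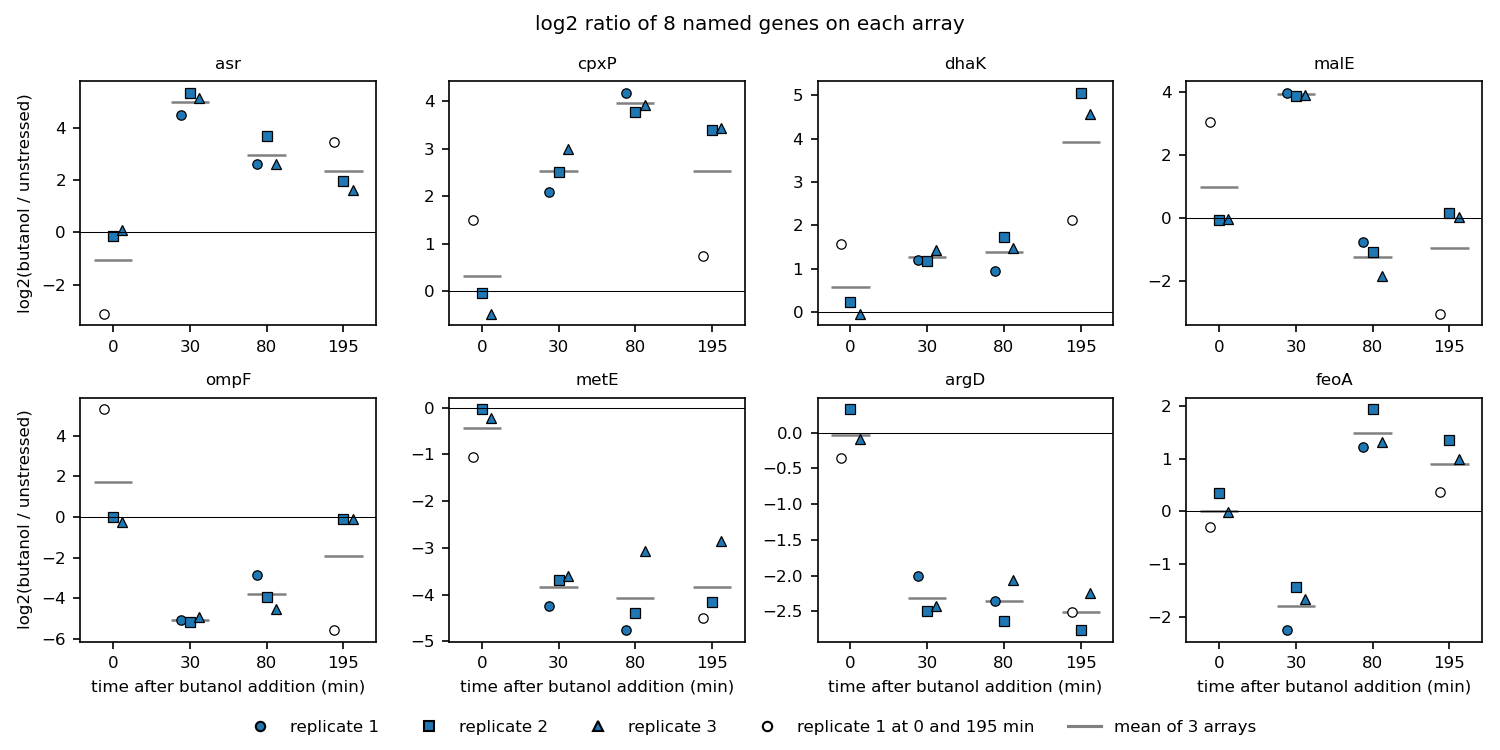
The log2 ratio of butanol over unstressed for 8 named genes against time in minutes, with 1 point per array, open points for replicate 1 at 0 and 195 min, and bars for the mean of 3 arrays. The genes metE, argD and asr keep their side of 0 from 30 to 195 min, while malE lies at 3.92 at 30 min and at -1.23 and -0.97 later.

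**Figure D4:**
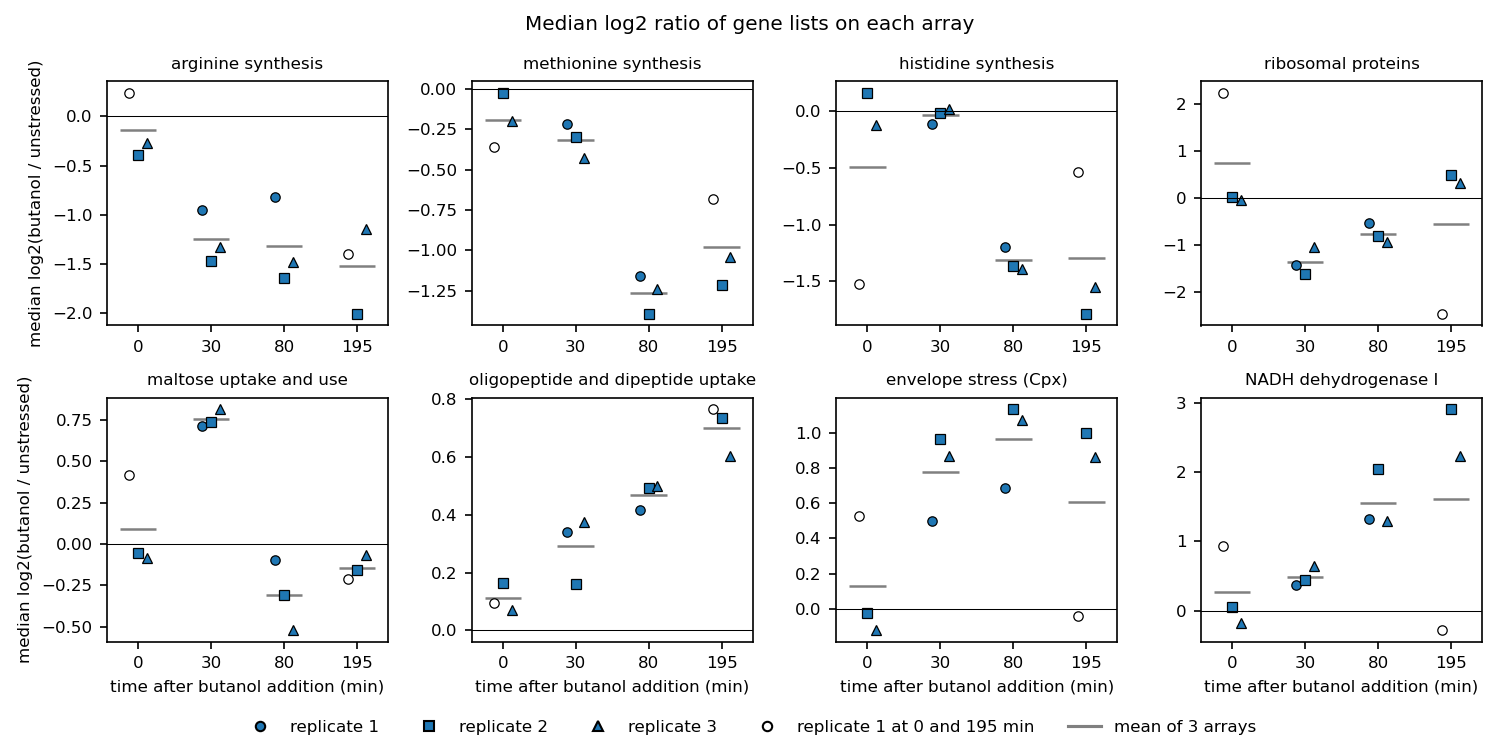
The median log2 ratio of butanol over unstressed of 8 gene lists against time in minutes, with 1 point per array, open points for replicate 1 at 0 and 195 min, and bars for the mean of 3 arrays. Arginine synthesis lies below 0 on every array from 30 min on, and the medians of ribosomal proteins and NADH dehydrogenase I on the open points at 195 min, -2.48 and -0.29, lie apart from the other arrays.

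The difference among 30, 80 and 195 min, and the change of the ratio from 30 to 195 min, ask whether the ratio of butanol over unstressed changed with time. The ferrous iron gene feoA fell at 30 min and rose at 80 min (1.49 ± 0.39) and 195 min (0.90 ± 0.50), a change of 2.68 from 30 to 195 min (adjusted p = 0.00208). Of 37 iron uptake genes 7 rose at 80 min, among them fhuF (1.60 ± 0.57), and 3 fell, among them the ferritin gene ftnA (-2.33 ± 0.63), with 11 and 3 adjusted over the list alone, but camera did not call the list at that time (adjusted p = 0.0582). The maltose genes went the other way: the ratios of malE, lamB and malF changed by -4.89, -4.26 and -3.90, and their values at 195 min were -0.97, -1.72 and -0.58. For lamB and malF the values at 195 min had n = 2. The dihydroxyacetone kinase gene dhaK changed by 2.65, the aspartase gene aspA by 2.51, the 2-oxoglutarate transporter gene kgtP by 2.27 and livH of branched-chain amino acid uptake by 2.26, while trpE changed by -3.33 and srlD by -2.88. The adjusted p-values of these 10 genes were 0.00208 to 0.0479. Of 14 maltose genes 5 changed downward, and 7 adjusted over the list alone (median -0.80, camera adjusted p = 2.24e-05, adjusted p = 0.622 with an estimated correlation). Of 14 branched-chain genes 2 changed upward, and 7 adjusted over the list alone (median 1.04, camera adjusted p = 0.000181, adjusted p = 0.646 with an estimated correlation). In all, 254 genes changed from 30 to 195 min, 103 upward and 151 downward, and 403 differed among the 3 times by limma's F test. Without both arrays that stood apart these counts were 1637, 875 upward and 762 downward, with all 254 among them, and 2170, so that the balance of direction turned, and with scan day as a block they were 129 and 251.

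Part of the response was shared between times. Transcripts of metE, hcp and argD fell and those of asr, rmf, aldB, spy and cpxP rose at all 3 times. In all, 92 genes were higher at 30, 80 and 195 min, where independent lists of the same sizes would share 4.01, and 77 were lower, where they would share 3.14. Leaving out both arrays that stood apart gave 259 higher, against 45.8, and 183 lower, against 44.7, a smaller excess relative to independent lists. The times share no arrays but share the estimate of the spread. Between 30 and 195 min 175 genes were higher at both times, 119 were lower at both, 15 were higher at 30 min and lower at 195 min, and 9 the reverse. In the fit without both arrays that stood apart these counts were 390, 288, 118 and 166.

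The other 10 lists were not set apart by camera at 30, 80 or 195 min in the fit of all arrays. Several were in the fit without both arrays that stood apart. Cytochrome bo oxidase was higher at 80 and 195 min (adjusted p = 3.52e-08 and 3.81e-07, 5 of 5 genes at both), ATP synthase at 80 and 195 min (0.0286 and 8.23e-07, 6 and 9 of 9 genes), and cytochrome bd and sigma E at 30 min (0.00421 and 0.013). Sigma S was higher at 80 min (0.0065) and lower at 195 min (5.41e-06, 19 of 25 genes), and pyrimidine synthesis at 30 min (0.0286), outer membrane genes at 80 min (0.00016) and cytochrome bd at 195 min (0.0434) were lower. Of lists called at another time, that fit also set apart NADH dehydrogenase I at 30 min (higher, 0.0225), alcohol and aldehyde enzymes at 80 min (higher, 0.00617), and at 195 min the TCA cycle (higher, 3.81e-06) and heat shock (lower, 0.00617). Each of these calls was lost with an estimated correlation in that fit (adjusted p = 0.401 to 0.839). Of 6 genes of the cytochrome bd oxidases, cydB (2.36 ± 0.16) and cydA (1.56 ± 0.15) rose at 30 min, with 2 adjusted over the list alone, and no member passed over all genes later. Of 5 cytochrome bo oxidase genes 1 rose, cyoC at 80 min (2.22 ± 0.25), and 5 adjusted over the list alone at that time. Of 9 ATP synthase genes, atpI rose at 80 min (1.46 ± 0.15) and 195 min (1.45 ± 0.41). In the sigma E envelope stress list 7 of 22 rose and 2 fell at 30 min, with 8 and 2 adjusted over the list alone, among them rseA (1.87 ± 0.14), rpoE (1.57 ± 0.24) and degP (1.54 ± 0.32). That list had 4 higher and 3 lower at 80 min, where its median was -0.07 and its mean and test were positive, and 2 and 2 at 195 min. Of 17 outer membrane genes 3 rose and 3 fell at 30 min, with a positive median (0.10) and a negative mean and test. At 80 min 4 of them fell, ompF (-3.77 ± 0.84), ompT, ompW (-1.99 ± 0.42) and lpp (-0.65 ± 0.14), and at 195 min 2 fell, ompA (-1.43 ± 1.16) and lpp (-0.95 ± 0.36).

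Of 25 sigma S genes, osmY fell at 30 min (-1.53 ± 0.08) and at 195 min (-1.68 ± 0.52), where 4 fell and 1 rose, and at 80 min katE rose (0.96 ± 0.21) and bolA fell (-0.94 ± 0.18). Of 17 acid resistance genes mdtF rose at 80 min (1.03 ± 0.24), and gadX (1.21 ± 0.56) and mdtF (0.78 ± 0.15) rose at 195 min. That list had a positive median (0.01) and a negative mean and test at 80 min. Of 10 pyrimidine genes, pyrC (-1.24 ± 0.04) and pyrD (-1.13 ± 0.37) fell at 30 min, pyrI (-0.71 ± 0.44) at 80 min and carB (-1.33 ± 0.79) at 195 min. Of 23 fatty acid and phospholipid genes, plsB rose at 30 min (0.63 ± 0.09) and 195 min (1.68 ± 0.35), and fabA fell at both (-0.73 ± 0.25 and -0.93 ± 0.09). Of 9 fatty acid degradation genes, fadL (-1.38 ± 0.59), fadB (-0.81 ± 0.31) and fadA (-0.67 ± 0.31) fell at 30 min, and no member passed limma's test later. In the fit of all arrays the camera adjusted p-values of these 10 lists were 0.0521 or higher at the 3 times. They were 0.416 or higher with an estimated correlation, for all 34 lists. The signs of the median and of the mean or the test also differed for other sugar uptake, cysteine, flagella and fatty acid degradation at 80 min, and for osmotic stress, alcohol and aldehyde enzymes, cytochrome bd and fatty acid degradation at 195 min, and camera called none of these lists at those times. For the change from 30 to 195 min they differed for fatty acid and phospholipid synthesis.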

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

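The tests of scan day, of reversed dyes, of cultures that differed beforehand and of a dye effect were chosen only after the result was seen, and the tests of exchanged RNA and the splits of the arrays were set before.

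The ratio of butanol over unstressed differed between times by a test of the difference itself, and a change in either channel can give such a difference. By limma's F test 403 genes differed among 30, 80 and 195 min, and the ratio of 254 changed from 30 to 195 min. The ratio changed upward for feoA (2.68), dhaK (2.65), aspA (2.51), kgtP (2.27) and livH (2.26) and downward for malE (-4.89), lamB (-4.26), malF (-3.90), trpE (-3.33) and srlD (-2.88), with n = 3 at both times except n = 2 at 195 min for lamB and malF.

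Camera set 11 lists apart for the change from 30 to 195 min. Upward median changes were those of branched-chain amino acid synthesis (1.04), ribosomal proteins (0.99), acid resistance (0.98), NADH dehydrogenase I (0.81) and cysteine synthesis and sulfate uptake (0.26). Downward ones were those of histidine synthesis (-1.16), maltose (-0.80), heat shock (-0.53), oxidative stress (-0.40), glycolysis and acetate (-0.33) and alcohol and aldehyde enzymes (-0.26). Their camera adjusted p-values were 2.24e-05 (maltose) to 0.0423 (alcohol and aldehyde), and 0.622 to 0.741 with an estimated correlation. The acid resistance change rested on 195 min replicate 1, whose median ratio was 1.30 against -0.59 and -0.10 on the other arrays of that time. With both arrays that stood apart left out its median change was 0.18 and its call was lost (adjusted p = 0.629), as were those of cysteine (0.23), alcohol and aldehyde (0.0874) and glycolysis and acetate (0.0725). In that fit the median changes of NADH dehydrogenase I, ribosomal proteins and heat shock were 1.79, 1.77 and -0.81. Camera then also called cytochrome bo oxidase (3.13, adjusted p = 2.26e-08), the TCA cycle (1.96, 1.92e-14), ATP synthase (1.74, 3.75e-08), cytochrome bd (-1.72, 2.48e-05), sigma S (-0.71, 0.000534), methionine synthesis (-0.65, 0.0369) and the anaerobic list (-0.26, 0.00652). Each of these 7 calls was lost with an estimated correlation (adjusted p = 0.364 to 0.501). Over all genes, 5 of 14 maltose, 8 of 30 oxidative stress, 4 of 22 glycolysis, 4 of 20 alcohol and aldehyde and 2 of 21 heat shock genes changed downward. Of the other lists 2 branched-chain, 2 acid resistance and 2 cysteine genes changed upward and 1 cysteine gene downward. Limma called 0 histidine, NADH dehydrogenase I and ribosomal genes over all genes, while adjusted over the list alone 7 of 8 histidine genes changed downward.

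The arrays labelled 0 min replicate 1 and 195 min replicate 1 stood apart from the other arrays of their times. A scan day effect would have set apart replicate 1 of 30 and 80 min, scanned on the same day, and their r with the other arrays of their times was 0.886 and 0.811. Reversed dyes at 195 min would have given a negative r with the other arrays of that time, and it was 0.0466, while cultures that differed beforehand would have carried the difference on, and the slope of the deviation at 195 min on the 0 min ratio was -0.965. An exchange of the butanol RNA was argued against by the single channels (difference of mean r -0.65), while an exchange of the unstressed RNA met the test set for it: in that channel mean r of 0 min replicate 1 was 0.463 with the 195 min arrays and -0.746 with its own time (difference 1.21), and that of 195 min replicate 1 was -0.033 with the 0 min arrays and -0.532 with its own (0.499). An exchange of the unstressed RNA may be part of the source, as a hypothesis that no label states. The r of channels were taken on each gene's deviation from its mean over all arrays, which lowers r between arrays. On that measure 195 min replicate 1 had no positive r with the 0 min arrays. The butanol channels had a mean r of only 0.0751 and 0.00199 with their own times. Because of the centring, these r values do not settle whether an exchange explains both arrays in full. Without centring, exchanged unstressed RNA would give 0 min replicate 1 the unstressed change to 195 min with its sign turned. Ribosomal, TCA and sigma S medians there were 2.23, 2.415 and -2.13. The changes on replicates 2 and 3 were -2.24 and -2.11, -2.75 and -2.77, and 1.54 and 1.64. It would give 195 min replicate 1 the butanol change: ribosomal -2.48 against -1.59 and -1.75, but NADH dehydrogenase I -0.29 against 0.25 and 0.39. The sum of the ratios of both arrays had r = 0.747 with the other 195 min arrays, which an exchange of either RNA could give. Beyond differing cultures no biological explanation was tested.

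A gene-specific dye effect was weighed for the genes called at 30, 80 and 195 min, because no dye swap was made. It would have given these genes a ratio of similar size at 0 min. In the mean of 0 min replicates 2 and 3, a ratio of the same sign and at least 0.5 of the size was present for 15 of 894 genes at 30 min, 16 of 828 at 80 min and 7 of 700 at 195 min, at most 1.93%, so a dye effect was argued against for the rest of these genes.

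The 6 arrays of a pair of times can be parted in 10 splits, which are too few for a share under 0.05. For the change from 0 to 30 min only 1 of the 10 splits, the real one, reached its count (412, highest other 0), for 0 to 80 min 1 split (337, highest other 0), and for 30 to 195 min 1 split (254, highest other 0). For 0 to 195 min 2 splits did: the real one gave 241, and the one that joined 0 min replicate 1 with 195 min replicates 2 and 3 gave 1065, several times as many, which points to a structure of the samples. That other split follows no scan day. For the difference among 30, 80 and 195 min 1 of 100 splits of the 9 arrays, the real one, gave 403 genes (highest other 209), so chance was argued against. The other splits were drawn at random, and not every possible split was tried. The split with 209 genes also kept the 30 min arrays together.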

How the results depend on the processing

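The alternatives that kept spots not found, used pixel means, left out both arrays that stood apart, or combined that with the replicate block were chosen only after the result was seen, and all others were planned.

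The counts at 30, 80 and 195 min stayed within 1.5 times with another or no background correction, median centring, print-tip loess, the deposited value table, dim spots left out, spots not found kept and pixel means: 824 to 922, 774 to 1064 and 665 to 808. The brightest probe could not be run, because each gene has 1 probe. Of 327 results of named genes under their alternatives, 8214 of 9150 values kept direction and call, 936 lost the call and 0 reversed. Of 52 called list results, 1290 of 1404 values kept both, 92 lost the call and 22 reversed.

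With scaling between arrays the counts of genes were 11 for butanol over unstressed at 0 min, 444 at 195 min and 648 for the change of the ratio from 0 to 30 min. With array weights they were 10 at 0 min, 2468 at 30 min, 1686 at 80 min and 2149 at 195 min, 1728, 1149 and 1644 for the changes from 0 to 30, 80 and 195 min, 2099 for the change from 30 to 195 min, and 2652 for the difference among 30, 80 and 195 min. The lowest weights were 0.117 for 0 min replicate 1 and 0.102 for 195 min replicate 1, and the others were 0.559 to 3.23. With both arrays that stood apart left out the counts were 1830, 2032 and 1769 for butanol over unstressed at 30, 80 and 195 min, 968, 1023 and 1277 for the changes from 0 min, 1637 from 30 to 195 min and 2170 among the 3 times. With the replicate block as well they were 2008, 2218, 1753, 1235, 1316, 1444, 1768 and 2397. The arrays that stood apart enter no mean at 30 or 80 min. Leaving them out therefore raised the counts of those ratios, to 1830 and 2032, only through the shared estimate of the spread. The SD among the 3 arrays of a time, for the median gene, was 0.144 at 30 min and 0.357 at 195 min. For the other counts the cause was not tested beyond the weights.

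With only the arrays of the times compared, butanol over unstressed gave 2018 genes at 30 min, 1292 at 80 min and 0 at 195 min in limma, where 668 had an unadjusted p under 0.05. The changes of the ratio from 0 to 80 min, 0 to 195 min and 30 to 195 min gave 27, 9 and 69. These fits had fewer samples and estimated the spread from them alone. With scan day as a block the counts were 595 at 30 min, 129 for the change of the ratio from 30 to 195 min and 251 for the difference among 30, 80 and 195 min, and the cause was not tested. Requiring a log2 ratio of at least 1 in size leaves fewer genes by construction: 318, 263 and 238 at 30, 80 and 195 min, 256, 197 and 137 for the changes from 0 min and 144 from 30 to 195 min.

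The labels do not say whether replicate numbers pair the arrays, and they were treated as unpaired because 8 of 18 pairs with the same number had r over 0.1, where every pair was required to, with a range of -0.855 to 0.41. The lowest values were those of 0 with 195 min, the times that hold the arrays that stood apart, and 30 with 80 min gave 0.41, 0.185 and 0.0692. The replicate block gave 805, 747 and 611 genes for butanol over unstressed at 30, 80 and 195 min and 0 at 0 min in limma, where 134 had an unadjusted p under 0.05.

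Leaving out 1 array at a time, where a time left with 2 arrays is assumed to vary like the others, gave 0 genes at 0 min in limma in each case, with 37 to 348 at an unadjusted p under 0.05. The ranges for butanol over unstressed were 367 (without 30 min replicate 3) to 1208 at 30 min, 217 (without 80 min replicate 2) to 1215 at 80 min and 344 (without 195 min replicate 3) to 1101 at 195 min, each highest without the array at 195 min that stood apart. Those of the change of the ratio were 125 to 769 from 0 to 30 min, 74 to 653 from 0 to 80 min, 67 to 432 from 0 to 195 min and 62 to 820 from 30 to 195 min, and for the difference among 30, 80 and 195 min 106 to 1044, with the highest again without 195 min replicate 1. Other arrays moved counts by over 1.5 times. At the single times these were 30 min replicates 1 (590) and 2 (370), 80 min replicate 3 (340) and 195 min replicate 2 (348). For 0 to 30 min they were 0 min replicates 1 (272) and 3 (267) and 30 min replicate 2 (140). For 0 to 80 min they were 0 min replicates 1 to 3 (212, 181 and 162), 30 min replicates 1 to 3 (211, 178 and 167) and 80 min replicate 3 (129). For 0 to 195 min they were 0 min replicates 2 and 3 (84 and 94), 30 min replicates 1 to 3 (159, 135 and 134), 80 min replicate 3 (157) and 195 min replicate 2 (82). For 30 to 195 min they were 0 min replicate 1 (398), 30 min replicates 1 and 2 (162 and 69) and 195 min replicates 2 and 3 (125 and 84), and for the difference among the times 0 min replicate 1 (621), 30 min replicate 2 (114), 80 min replicates 2 and 3 (208 and 203) and 195 min replicate 3 (225).

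The 52 called results of gene lists at each time were 49 to 58 without 1 array, 36 with fry, and 0 with an estimated correlation, where the lowest adjusted p was 0.416 in limma's camera. The change from 0 min gave 37 calls: of the 43 called ratios at 30, 80 and 195 min it kept 33 and lost 10, and it called 4 others (the TCA cycle at 30 min, sigma S and alcohol and aldehyde enzymes at 80 min, and branched-chain synthesis at 195 min).

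Medians of 7 called list results changed sign. At 0 min with array weights they were -0.016 for the TCA cycle (0.74 with all arrays alike), 0.026 for heat shock (-0.37), 0.037 for sigma S (-0.67) and 0.038 for histidine synthesis (-0.52). Both without 0 min replicate 1 and with both arrays left out, they were -0.049, 0.086, 0.10 and 0.055, and -0.0071 for ribosomal proteins (0.74). With the replicate block and both left out they were -0.0097 for the TCA cycle, 0.050 for sigma S, 0.075 for histidine synthesis and -0.0011 for other sugar uptake (0.27). At 195 min ribosomal proteins (-0.58) had 0.27 with array weights, 0.41 without 195 min replicate 1 and with both left out, and 0.47 with the block as well. Over the leave-one-out fits the medians ranged from -0.049 to 1.14 (TCA cycle), -0.63 to 0.086 (heat shock), -1.15 to 0.10 (sigma S), -0.86 to 0.055 (histidine), -0.0071 to 1.14 (ribosomal, 0 min), 0.078 to 0.37 (other sugar uptake) and -1.17 to 0.41 (ribosomal, 195 min). The values per array show that 1 array of each of these times set these signs, except for other sugar uptake, where the cause was not tested.

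Signal limits what the arrays can show: 54.6% (80 min replicate 2) to 99.5% of spots were above background in the butanol channel and 68.9% (195 min replicate 3) to 99.1% in the unstressed one. The SD among the 3 spots of the median gene was at most 0.105 on the 0 min arrays, 0.0931 at 30 min, 0.177 at 80 min and 0.209 at 195 min, on each array below the SD among the 3 arrays of its own time (0.291, 0.144, 0.222 and 0.357).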

Other observations

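The test of the change in unstressed cells was set before its result, and showing the single channels of replicates 2 and 3 was chosen only after the result was seen.

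Each channel of replicates 2 and 3 was also followed by itself from 0 min, with n = 2 and no test. In unstressed cells the median log2 change from 0 to 195 min was -3.73 and -3.83 for cytochrome bo oxidase, -3.79 and -3.29 for ATP synthase, -2.75 and -2.77 for the TCA cycle and -2.39 and -1.74 for NADH dehydrogenase I. In butanol it was -0.32 and -1.16, -2.10 and -1.92, -0.98 and -1.42, and 0.25 and 0.39. Sigma S genes changed by 1.54 and 1.64 in unstressed cells and by 0.29 and 0.86 in butanol, and histidine genes by 1.04 and 1.72 and by -1.22 and -0.10. Ribosomal protein genes changed by -2.24 and -2.11 in unstressed cells and by -1.59 and -1.75 in butanol. At 80 min TCA cycle genes had changed by -1.40 and -1.84 in unstressed cells and by -0.26 and -0.92 in butanol, so their higher ratio at that time came with a fall in both. At 30 min ribosomal protein genes had changed by 0.24 and 0.08 in unstressed cells and by -1.32 and -0.99 in butanol. Branched-chain genes had changed by 0.17 and 0.10 in unstressed cells and by -1.46 and -1.32 in butanol at 30 min. At 195 min these changes were -1.77 and -1.43, and -1.63 and -1.25. The upward change of their ratio thus came with a fall in unstressed cells.

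The SD over genes of the change from 0 min was 0.297 in unstressed cells and 0.639 in butanol at 30 min, 0.640 and 0.762 at 80 min, and 1.15 and 0.915 at 195 min. A hypothesis is that butanol-treated cells lacked part of the change with time of unstressed cells, so that part of the ratio at 195 min may come from the unstressed culture. Across genes, r between the unstressed change from 0 to 195 min in 1 replicate and the 195 min ratio in the other was -0.526 and -0.611. Noise of the 195 min unstressed channel that is independent between arrays would give this only within a replicate, where r was -0.574 and -0.556, and so was argued against by -0.526. A bias common to both 195 min unstressed channels would also give it across replicates and was not tested. Growth of the cultures was not analysed here, and the hypothesis was tested on the same data.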
